A study of Mus musculus with 24 samples.

How the data were processed

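RNA was measured in livers of individual mice, WT and hepatocyte-specific Egfr knockout, at 0, 1, 3 and 12 h of an acetaminophen experiment at 500 mg/kg, with 3 mice in each of 8 groups. Per the labels, RNA was extracted with TRIzol, the molecule is polyA RNA, and the libraries were sequenced on an AVITI instrument. For each of the 24 libraries the authors deposited raw counts per gene made with STAR on genome build mm39; the STAR version and the gene annotation are not given in the sources used here. Each file holds counts for 50657 gene symbols and 4 lines that name no gene (unmapped, multimapping, no feature, ambiguous). It has 3 count columns: reads without regard to strand, reads on the gene's strand and reads on the opposite strand. No genome positions are given, because the reference at hand is of another build.

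The count column was set by a rule written before the files were read: the gene-strand column only if at least 80% of the strand-assigned counts of every library lay on the gene's strand, and otherwise the unstranded column. The share was 72.8% to 81.0% and 1 library passed, so the unstranded column is the main choice. A single locus, AY036118, which overlaps ribosomal RNA, held most of the opposite-strand counts, and without it the share was 95.9% to 96.6%. The gene-strand column was therefore added as an alternative after the data were seen. Of 165 genes named in the tests, 16 had more counts on the opposite strand than on their own, and the report marks them where they appear.

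Reads in the files numbered 20.0 to 36.2 M per library. Of these 17.6% to 22.5% were counted on genes, 26.3% to 30.8% were ambiguous, 21.2% to 22.7% met no feature, 19.2% to 23.7% were unmapped and 7.23% to 8.70% mapped to several places. Counts on genes ran from 3.54 to 7.58 M. The 10 highest genes of each library took 52.7% to 63.5% of these. At 1.75 to 4.37 M counts outside the mitochondrial ribosomal RNA, genes of a few CPM rest on few reads, and replicate pairs differed by 2.41 to 23.8 times the counting variance (chi-squared per degree of freedom). Pearson correlation of log2 CPM between replicates was 0.950 to 0.982.

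Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr on the 8 groups, which left 13204 genes with at least 99.4% of the counts of each library. Library sizes were scaled by TMM, dispersions were estimated with the robust option, and a quasi-likelihood model with 1 mean per group and no covariate was fitted to all 24 libraries. The contrasts were KO vs WT at each time, each later time vs 0 h within each genotype, and the KO response minus the WT response at 1, 3 and 12 h, each with a two-sided F-test and Benjamini-Hochberg adjustment over all tested genes at 0.05. KO vs WT averaged over the 4 times was added after the data were seen. Mice at different times are different animals, and the 3 responses of a genotype share their 0 h mice. Egfr was also tested by 100000 permutations of the genotype labels within times on log2(CPM + 1). CPM values use the TMM-scaled library sizes. Principal components were computed on log2 CPM with a prior count of 2. Responses of the genotypes were compared across genes by correlation, slope and shared calls, without a p-value.

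Gene lists were written before the files were read, 32 gene groups and 11 sets of cell type markers. The 35 lists with at least 5 tested members were tested with camera of limma 3.58.1 on voom values with an inter-gene correlation of 0.01, adjusted over the lists within a contrast. Camera with a correlation estimated from the data, and fry, a test of the direction of the set's own genes, were run beside it, as set before the files were read. "Adjusted over the list alone" means that the edgeR p-values of the members were adjusted among themselves.

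Genes were named by a rule fixed before the files were read. For KO vs WT and for WT responses these were up to 6 genes in each direction with the largest change among those with adjusted p under 0.05, a mean of at least 5 CPM in the higher group and no overlap of the 3 and 3 libraries. For KO responses the number was 3 in each direction and for differences of response 5, there with at least 5 CPM in the highest of the 4 groups. The rule added up to 4 members of each gene list by smallest p, called or not, and 2 markers of each cell type list. Of the gene list members the text kept the called ones. Predicted genes named by clone or number were passed over, and genes chosen after their values were seen are marked. Some list members the rule names are left out of the text to keep it short, and a few genes it names are not reported here.

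The other settings written down beforehand were RLE scaling, library size alone, no low-count filter, a filter of at least 1 CPM in 3 libraries, DESeq2 1.42.0, a fit of only the groups compared, the replicate number as a block, and leaving out each library in turn. Added after the data were seen were the gene-strand column, removal of genes linked to ribosomal RNA, and removal of WT 3 h replicates 2 and 3 together, which leaves 1 library in that group and takes the spread from the other groups. Each contrast was also refitted with other splits of the same libraries into groups of 3, 10 splits for a contrast of 2 groups and 100 for differences of response and the averaged contrast. The method was tested on simulated data in which 200 genes changed. In KO vs WT at 1 h it found 91.8% of changes of log2 size 2 and 54.1% of size 1 among 98 tested genes each, and called 6 of 12656 unchanged genes. For a difference of response it found 69.4% and 31.6%. The simulated genes were drawn independently of each other and with no change over time. Shifts shared by many genes of 1 mouse were thus absent, and these rates need not hold for the real data. No sample was left out of the main analysis.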

Results

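Gene expression was measured by bulk RNA sequencing in livers of wild-type (WT) mice and of mice that lack Egfr, the gene for the epidermal growth factor receptor, in hepatocytes only (KO). The mice received an overdose of acetaminophen, 500 mg/kg, a drug that injures the liver through a reactive metabolite made mainly by Cyp2e1 in hepatocytes around the central vein. Livers were taken at 0, 1, 3 and 12 h, with 3 mice for each genotype and time, which makes 8 groups and 24 libraries. The 6 h and 24 h times named in the series text are not among the samples and are not analysed here. The labels do not say whether the 0 h mice were given the drug or its vehicle. All mice at 1, 3 and 12 h had the drug, with no untreated mice at those times. A response below is the change from 0 h, in which the drug cannot be told apart from time of day or handling. Gene counts per library ran from 3.54 to 7.58 M (median 5.93 M), with the lowest total in KO 12 h replicate 3. Ribosomal RNA of the mitochondrion took 39.6% to 50.4% of these counts, which leaves 1.75 to 4.37 M counts on other genes. Levels are in CPM, counts scaled by library size after TMM scaling, and given as mean ± SD of 3 mice. Changes are log2 fold changes with their standard error (SE).

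The libraries separated first by time. On the first principal component, with 33% of the variance, the 0 h libraries of both genotypes lay between -39.7 and -33.1 and the 12 h libraries between 43.4 and 52.4, with 1 h and 3 h between them. The third component, with 6.02% of the variance, set apart WT 3 h replicates 2 and 3 at 35.6 and 35.2, whereas WT 3 h replicate 1 lay at 0.34. No component among the first 4 separated the genotypes at every time. On the third, KO lay below WT at 0 h (-6.40 to -2.01 against 3.15 to 10.3) and 3 h (-14.6 to -1.16 against 0.34 to 35.6). At 1 h KO lay above WT on it (-2.05 to 3.69 against -22.4 to -14.8), and at 12 h the genotypes overlapped.

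**Figure D1:**
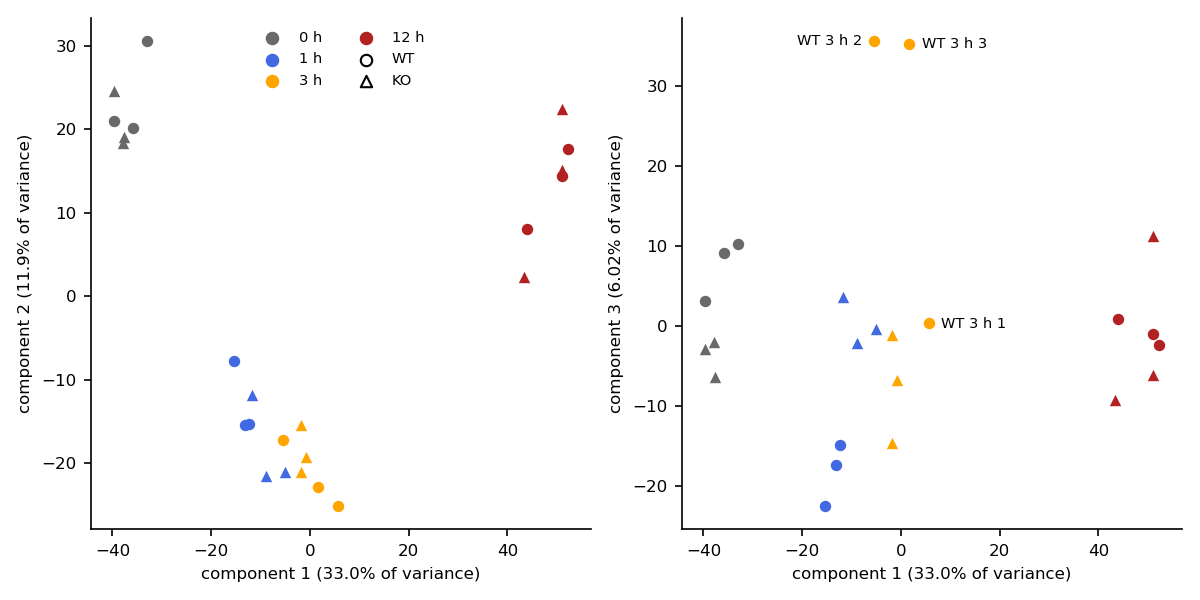
Principal component analysis of log2 CPM over the 13204 tested genes; each point is 1 library, colour gives the time and the symbol the genotype. The left panel shows components 1 and 2 and the right panel components 1 and 3, where WT 3 h replicates 2 and 3 lie at 35.6 and 35.2 on the third component.

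The first question was whether Egfr itself was lower in the KO livers. Egfr averaged 393 ± 63.9 CPM in WT and 82.4 ± 25.3 CPM in KO at 0 h, 380 ± 41.6 and 209 ± 110 CPM at 1 h, 464 ± 165 and 179 ± 94.4 CPM at 3 h, and 223 ± 33.9 and 75.4 ± 38.0 CPM at 12 h. The groups did not overlap at 0, 3 and 12 h. At 1 h the library labelled KO 1 h replicate 1 had 335 CPM, above the lowest WT 1 h library (332 CPM) and above the highest of the other 11 KO libraries (271 CPM), so its Egfr level does not follow its label. Over all 24 libraries the KO minus WT difference of log2(CPM + 1), averaged over the 4 times, was -1.59 (two-sided permutation test within times, p = 1e-05). That is the smallest value 100000 random draws can give, and no draw was as large. Exchanging the library labelled KO 1 h replicate 1 with the lowest WT 1 h library would give a larger difference, so the exact p is above this estimate. In the model across all genes Egfr did not pass at any single time: its log2 fold change was -2.25 at 0 h (adjusted p = 0.0946), -0.87 at 1 h (0.54), -1.37 at 3 h (0.216) and -1.55 at 12 h (0.243). At 0 h it passed with DESeq2 (adjusted p = 0.000468) and with only the groups compared in the fit (0.00262). Why reads of Egfr remain in KO livers was not tested.

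**Figure D2:**
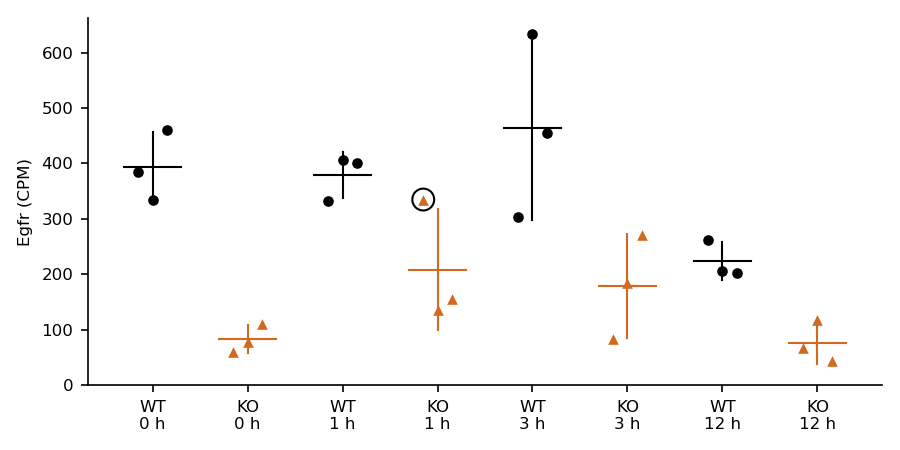
Egfr in each of the 24 libraries in CPM on a linear axis that starts at 0; points are libraries, horizontal bars are group means and vertical bars 1 SD of 3 mice. The library labelled KO 1 h replicate 1, marked with a ring, lies at 335 CPM among the WT libraries of its time.

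At 1 h after the drug, WT livers had raised the immediate early genes, which respond within minutes to stress and growth signals. Many of them encode transcription factors. Egr1 rose from 5.96 ± 1.76 to 200 ± 13.6 CPM (log2 fold change 5.04, SE 0.419) and Jun from 10.1 ± 2.67 to 219 ± 37.9 CPM (4.43, SE 0.254). Zfp36, which speeds the decay of cytokine mRNA, rose by 1.82. Of the 19 tested immediate early genes 12 rose and none fell (14 adjusted over the list alone; adjusted p = 1.06e-14, and adjusted p = 0.1 with an estimated correlation). Of 17 genes of the integrated stress response, the program behind the translation brake eIF2 alpha, 5 rose, among them Atf4 (1.03), Atf3 (3.39) and Gdf15 (3.40), and 1 fell (6 and 2 adjusted over the list alone). The list test did not pass (adjusted p = 0.113). Heat shock genes rose as a list, with 4 of 15 called (5 adjusted over the list alone; adjusted p = 3.12e-06, and adjusted p = 0.25 with an estimated correlation), led by the chaperone Hspa1b at 2.45 and its partner Bag3 at 0.74. Targets of the fatty acid receptor PPARA and genes of fatty acid oxidation also rose, 6 of 24 (7 adjusted over the list alone; adjusted p = 4.85e-07, and adjusted p = 0.322 with an estimated correlation). Among them were Pdk4 (2.59), Acot2 (1.83) and the lipid droplet protein Plin2 (1.27). The fatty acid elongase Elovl5 rose by 0.94 and Btbd19 by 3.64.

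Lower in WT at 1 h were clock, drug metabolism and Kupffer cell genes. Of 19 clock genes 10 fell and 3 rose (12 and 4 adjusted over the list alone; adjusted p = 0.000517, and adjusted p = 0.248 with an estimated correlation): Per3 fell by 2.56, Ciart by 2.17 and Tef by 1.44, while Bmal1, which runs opposite to them over the day, rose by 2.10. Cyp3a25 fell from 984 ± 25.5 to 494 ± 131 CPM, and 5 of 18 phase I drug metabolism genes fell (5 adjusted over the list alone; adjusted p = 0.000904, and adjusted p = 0.322 with an estimated correlation). Of the 11 Kupffer cell markers 6 fell (9 adjusted over the list alone; adjusted p = 6.63e-06, and adjusted p = 0.322 with an estimated correlation), with the scavenger receptor Marco at -2.65 (SE 0.569) and Clec4f at -0.59. Spred1 (-0.89) and Spry4 (-1.29), inhibitors of the pathway below EGFR, fell, as did its partner receptor Erbb3 (-0.60). The kinase Map2k6 fell by 3.39 and the histone methyltransferase Setdb2 by 2.96. Of the loci named by the rule, Zbtb45 (-2.72) and Gpr17 (-2.49) had 11.5% and 0.589% of their stranded counts on the gene's own strand, so most of the reads counted for them lie on the other strand. In all 1068 genes passed, 540 higher and 528 lower. The count was 710 without WT 0 h replicate 3 and 684 without WT 1 h replicate 1. Clec4f lost its call without WT 0 h replicate 2 (adjusted p = 0.0959) or 3 (0.259) and without WT 1 h replicate 1 (0.145), 2 (0.128) or 3 (0.0897), and Spry4 without WT 0 h replicate 1 (0.0586).

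At 3 h the acute phase genes, the plasma proteins and iron and defence genes that hepatocytes make under inflammatory signals, stood far above 0 h in WT. Of 22 tested members 19 rose (20 adjusted over the list alone): Hp from 381 ± 46.5 to 1234 ± 496 CPM (log2 fold change 1.70, SE 0.189), Itih3 by 1.71, Serpina3n by 2.00 and Lcn2 by 6.01. The list passed (adjusted p = 2.19e-12, and adjusted p = 0.182 with an estimated correlation). Most of the rise lay in 2 of the 3 mice: the mean log2(CPM + 1) of the list was 8.55 and 8.67 in WT 3 h replicates 2 and 3, 6.23 in replicate 1, and 5.74 to 7.18 in the other 21 libraries. Plasma proteins outside this list rose too, 9 of 21 (12 adjusted over the list alone; adjusted p = 1.79e-05, and adjusted p = 0.165 with an estimated correlation), among them Alb (0.76), Ahsg (0.79) and Ambp (0.92). Without those 2 libraries, which leaves 1 WT mouse at 3 h and takes the spread from the other groups, neither list passed (both adjusted p = 0.131), and Lcn2, Itih3, Serpina3n, Alb, Ahsg and Ambp were no longer called, while Hp was (0.80, adjusted p = 0.000819). Sftpa1 rose by 4.55. Of 5 red blood cell genes 1 rose (3 adjusted over the list alone; adjusted p = 0.0707).

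**Figure D3:**
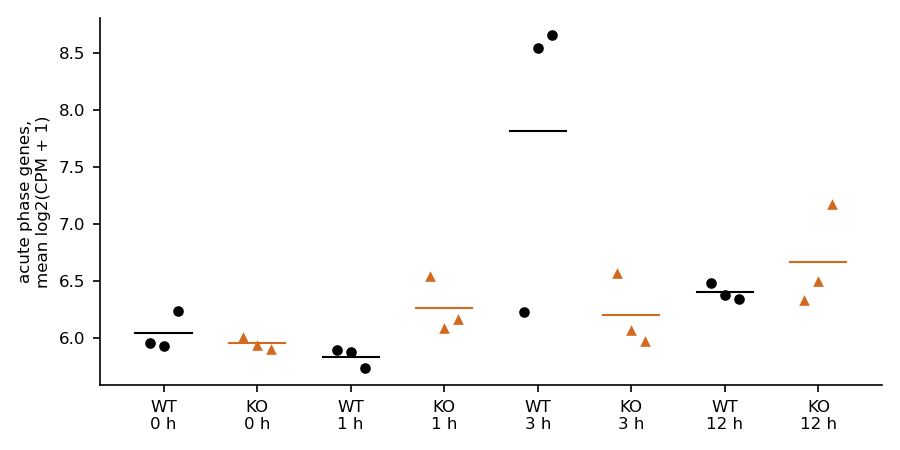
Mean log2(CPM + 1) of the 22 tested acute phase genes in each of the 24 libraries; points are libraries and horizontal bars group means. WT 3 h replicates 2 and 3 lie at 8.55 and 8.67, WT 3 h replicate 1 at 6.23, and no other library is above 7.18.

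Stress programs were also up at 3 h in WT, and most were still called in the fit that keeps 1 WT mouse at this time. Immediate early genes rose, 14 of 19 (14 adjusted over the list alone; adjusted p = 1.56e-14, and adjusted p = 0.052 with an estimated correlation), with Jun at 4.04. Of 17 integrated stress response genes 9 rose and 1 fell (11 and 2 adjusted over the list alone; adjusted p = 0.000335, and adjusted p = 0.153 with an estimated correlation): Atf4 by 1.28, Atf3 by 3.92 and the glutathione-degrading enzyme Chac1 by 2.62. Of 13 p53 targets 4 rose (5 adjusted over the list alone; adjusted p = 0.0033, and adjusted p = 0.069 with an estimated correlation), among them the cell cycle inhibitor Cdkn1a (3.11) and Trp53inp1 (1.66). Heme oxygenase, Hmox1, rose from 9.39 ± 1.52 to 59.7 ± 31.2 CPM. Hepatocyte transcription factors fell, 7 of 16 (9 adjusted over the list alone; adjusted p = 5.43e-05, and adjusted p = 0.0358 with an estimated correlation), including Ppara (-1.23), Foxa1 (-0.99) and the drug sensor Nr1i3 (-1.66). Bmal1 (2.18) and Nfil3 (1.57) rose. The flavin monooxygenase Fmo1 fell by 0.93, and 4 of 15 heat shock genes fell, Chordc1 by 1.11 and Hsph1 by 1.26 among them (5 adjusted over the list alone; adjusted p = 0.0262, and adjusted p = 0.618 with an estimated correlation). Without WT 3 h replicates 2 and 3, Nr1i3 (adjusted p = 0.0977), Hsph1 (0.257) and the heat shock list (0.198) missed. The heat shock call was also lost without WT 0 h replicate 1 (adjusted p = 0.052) or 2 (0.118) and without WT 3 h replicate 3 (0.102).

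By size alone the largest 3 h changes in WT included Clec2d, which fell from 97.0 ± 13.8 to 11.1 ± 1.80 CPM, and genes whose identity is uncertain. The pseudogenes Cyp2d38-ps (-2.73) and Cyp2d37-ps (-2.70) fell, Serpina3l-ps went from 0.115 ± 0.106 to 5.00 ± 3.20 CPM, and the unnamed locus LOC118567560 from 0.183 ± 0.215 to 5.17 ± 2.79 CPM. Ptprz1 (5.34), Zbtb45 (-3.05), Obox4-ps2 (-2.42) and Nlrp5-ps (-2.41) were called as well, but 2.12%, 11.5%, 0% and 3.27% of their stranded counts lay on the gene's own strand. In all 1865 genes passed, 961 higher and 904 lower, and 1027 passed without WT 3 h replicates 2 and 3. With only the groups compared in the fit the count was 1198. With library size as the only scaling 689 were higher and 1191 lower.

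At 12 h in WT all 19 immediate early genes rose (19 adjusted over the list alone; adjusted p = 7.2e-31, and adjusted p = 0.00366 with an estimated correlation), with Jun at 462 ± 58.4 CPM (5.50, SE 0.263), Zfp36 at 241 ± 39.5 CPM (2.95) and Fos at 100 ± 24.1 CPM from 0.307 ± 0.275. Of 17 integrated stress response genes 10 rose and 1 fell (10 and 1 adjusted over the list alone; adjusted p = 2.15e-05, and adjusted p = 0.0509 with an estimated correlation): Atf3 by 7.42, Gdf15 by 6.18 and Ddit3 by 2.92. The p53 targets rose, 6 of 13 (6, with 1 lower, adjusted over the list alone; adjusted p = 0.000261, and adjusted p = 0.0317 with an estimated correlation), with the p53 inhibitor Mdm2 at 2.77 and Btg2 at 5.03, but the list missed with no low-count filter (adjusted p = 0.0641). Of 10 cytokine and NF-kB genes 5 rose and 1 fell (5 and 1 adjusted over the list alone; adjusted p = 0.000457, and adjusted p = 0.0509 with an estimated correlation), with the chemokine Cxcl10 at 4.52 and Nfkbiz at 3.42. Targets of the ERK kinases below EGFR rose, 9 of 14 (10 adjusted over the list alone; adjusted p = 1.08e-05, and adjusted p = 0.0675 with an estimated correlation), among them Epha2 (2.54), Ier3 (3.71) and Dusp6 (2.64). The EGFR ligands Areg and Hbegf reached 3.71 ± 1.34 and 5.14 ± 2.37 CPM from 0.0874 ± 0.0757 and 0.175 ± 0.151, and Erbb3 fell by 1.54. The NRF2 targets Hmox1 (4.69) and Osgin1 (3.93), part of the defence against oxidants, rose with 5 of 22 list members (5 adjusted over the list alone; 1 fell; adjusted p = 0.00227, and adjusted p = 0.337 with an estimated correlation), a list that missed with no low-count filter (0.314).

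Genes of the hepatocytes around the central vein were lower in WT at 12 h, 8 of 17 (9 adjusted over the list alone; 1 rose; adjusted p = 0.00177, and adjusted p = 0.369 with an estimated correlation). The glutamate transporter Slc1a2 fell from 242 ± 29.6 to 7.57 ± 4.87 CPM (-5.03, SE 0.494), glutamine synthetase Glul by 2.10 and Oat by 1.45. Hepatocyte transcription factors fell, 8 of 16 (10, with 2 higher, adjusted over the list alone; 1 rose; adjusted p = 0.00227, and adjusted p = 0.0509 with an estimated correlation), among them Ppara (-1.42) and Nr5a2 (-1.05). Cyp2e1 fell from 3717 ± 542 to 1959 ± 86.4 CPM and Cyp2c37 by 1.25. Of 18 phase I genes 6 fell (6, with 1 higher, adjusted over the list alone; adjusted p = 0.0204, and adjusted p = 0.376 with an estimated correlation). The wound genes Tnfrsf12a (4.52) and Ccn1 (4.09) rose, as did Sox9 (3.77), a marker of bile duct and progenitor-like cells, and Socs3 (4.21), the brake on cytokine signalling. Crp fell by 0.78 and the interferon-induced Oasl1 rose by 2.62. Bmal1 rose by 2.42 and Nr1d1, which represses Bmal1, by 0.83. The Nr1d1 call was lost without WT 0 h replicate 1 (adjusted p = 0.103) or 2 (0.0523) and without WT 12 h replicate 1 (0.0768) or 3 (0.0788). From near 0, Garin1a reached 31.7 ± 14.7, Ccdc180 21.3 ± 7.02, Krt78 19.5 ± 2.98 and Lsmem1 14.1 ± 2.39 CPM. LOC118568359 (-3.74), Setdb2 (-3.46) and Gvin3 (-2.75) fell, with Tulp2 (-2.71) and Obox4-ps2 (-3.27), which had 1.25% and 0% of stranded counts on their own strand. In all 3381 genes passed, 1772 higher and 1609 lower. With library size as the only scaling the median of all genes moved by -0.367 and 17.6% of 5324 calls were higher, against 52.4% here, so these directions are relative to the middle of all genes.

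KO livers raised the same immediate early list at 1 h. Of 19 members 11 rose (13 adjusted over the list alone; adjusted p = 2.26e-16, and adjusted p = 0.0326 with an estimated correlation): Jun went from 11.3 ± 3.20 to 216 ± 20.0 CPM (4.26, SE 0.25), Egr1 rose by 4.61, Zfp36 by 2.04 and Ier2 by 2.18. Of 17 integrated stress response genes 6 rose (7, with 1 lower, adjusted over the list alone; adjusted p = 0.000148, and adjusted p = 0.125 with an estimated correlation), with Atf4 (1.25), Ddit3 (1.92) and Gdf15 (3.50). Osgin1 rose by 2.02 and Hmox1 by 2.41. Hepatocyte transcription factors fell, 8 of 16 (10 adjusted over the list alone; adjusted p = 1e-07, and adjusted p = 0.00329 with an estimated correlation), among them the pioneer factors Foxa2 (-1.51) and Foxa1 (-0.91), and Ppara (-0.79). Of 19 clock genes 10 fell and 3 rose (13 and 4 adjusted over the list alone; adjusted p = 0.000602, and adjusted p = 0.125 with an estimated correlation): Per2 (-1.62), Usp2 (-2.21) and Tef (-0.97) fell and Bmal1 rose by 1.72. Socs3 fell by 1.37. Dmbt1, a secreted mucin-like protein, had 0.348, 250 and 85.9 CPM in the 3 KO 1 h libraries, so its call rests on 2 mice, and the intestinal mucin Muc3a was called with an SD above its mean (6.03 ± 7.79 CPM). Of 3 other loci named by the rule, Rbpjl had no counts at KO 0 h and 6.10 ± 2.81 CPM at 1 h, Egfros fell by 2.42 and St8sia3 by 2.28; 0.219%, 0.238% and 21.1% of their stranded counts lay on their own strand. In all 1001 genes passed, 521 higher and 480 lower, with the library labelled KO 1 h replicate 1 included, and 567 passed without KO 1 h replicate 2. Muc3a lost its call without KO 0 h replicate 1 (adjusted p = 0.0579), 2 (0.0599) or 3 (0.0656), and Socs3 without KO 0 h replicate 2 (0.0655).

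At 3 h in KO the same programs stayed up and no acute phase gene rose. Immediate early genes rose, 11 of 19 (15 adjusted over the list alone; adjusted p = 1.16e-20, and adjusted p = 0.0255 with an estimated correlation), with Egr1 at 187 ± 23.8 CPM (4.60), Jun (4.45) and Zfp36 (2.27). Of 17 integrated stress response genes 7 rose (8, with 1 lower, adjusted over the list alone; adjusted p = 1.75e-06, and adjusted p = 0.0493 with an estimated correlation), among them Atf3 (4.54) and Gdf15 (4.29). Hmox1 rose from 6.99 ± 2.46 to 87.1 ± 35.8 CPM, Osgin1 by 1.94 and Gclc, the rate-limiting enzyme of glutathione synthesis, by 0.82. Of 22 acute phase genes none rose and 1 fell at this time (adjusted p = 0.69). Hepatocyte transcription factors fell, 5 of 16 (7 adjusted over the list alone; adjusted p = 0.00151, and adjusted p = 0.0493 with an estimated correlation), with Ppara at -0.69 and Nr5a2 at -0.57. Errfi1, an inhibitor of EGFR, rose by 0.50 and Spry4 fell by 1.97, and Bmal1 rose by 1.86. Of 21 cholesterol synthesis genes 5 fell (9 adjusted over the list alone; adjusted p = 0.00026, and adjusted p = 0.939 with an estimated correlation), a list call that ended without KO 0 h replicate 1 (adjusted p = 0.214). LOC118567560 went from 0.174 ± 0.187 to 5.56 ± 0.465 CPM. Notch3 (-3.42), Flrt1 (-2.61), Egfros (-2.26) and Phgdh (3.23) were called with 30.5%, 30.3%, 0.238% and 2.19% of stranded counts on their own strand. In all 1314 genes passed, 675 higher and 639 lower; 863 passed without KO 3 h replicate 2 and 715 without replicate 3.

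The 12 h response of KO livers had the shape of the WT response. All 19 immediate early genes rose (19 adjusted over the list alone; adjusted p = 1.9e-28, and adjusted p = 0.00557 with an estimated correlation), with Jun at 451 ± 49.4 CPM (5.33, SE 0.259), Fos at 67.8 ± 14.6 CPM, and Fosb at 7.56 ± 4.65 CPM from no counts at 0 h. Integrated stress response genes (11 of 17 rose, 12 with 1 lower adjusted over the list alone), p53 targets (5 of 13 rose and 2 fell, 6 and 2 adjusted over the list alone), cytokine and NF-kB genes (6 of 10 rose, 8 adjusted over the list alone) and ERK targets (11 of 14 rose, 11 adjusted over the list alone) passed, with adjusted p = 0.024, 0.024, 0.024 and 0.0379 with an estimated correlation. With no low-count filter the p53 list missed (adjusted p = 0.678). Among them were Atf3 (7.91), Ddit3 (3.91), Mdm2 (2.37), Btg2 (5.21), Cxcl10 (5.63), Ier3 (4.48) and Dusp5 (4.97). Hbegf rose by 3.36, Areg reached 3.92 ± 1.97 CPM from no counts at 0 h, and Erbb3 fell by 1.15. Hmox1 (5.26), Osgin1 (4.13), Tnfrsf12a (4.49), Ccn1 (3.02), Thbs1 (3.81), Sox9 (2.53) and Socs3 (3.14) rose.

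Central vein genes fell in KO at 12 h, 9 of 17 (9 adjusted over the list alone; adjusted p = 0.000403, and adjusted p = 0.252 with an estimated correlation): Slc1a2 from 258 ± 65.1 to 8.77 ± 9.07 CPM (-4.78), Glul by 2.06 and Oat by 1.93. Hepatocyte transcription factors fell, 11 of 16 (11 adjusted over the list alone; adjusted p = 1.33e-05, and adjusted p = 0.0114 with an estimated correlation), with Ppara (-1.47) and Nr5a2 (-1.20). Of 18 phase I genes 9 fell and 1 rose (10 and 1 adjusted over the list alone; adjusted p = 0.00194, and adjusted p = 0.252 with an estimated correlation), among them Cyp2a5 (-2.37) and Cyp2c37 (-1.58). Bile acid synthesis and transport genes fell, 9 of 21 (12 adjusted over the list alone; adjusted p = 0.00114, and adjusted p = 0.17 with an estimated correlation), with Akr1d1 (-1.53) and the bile acid receptor Nr1h4 (-0.84). Klhdc7a (-3.69) and LOC118568359 (-4.27) fell, and Bmal1 (1.84) and Nr1d1 (0.98) rose. The stellate cell marker Dcn rose by 0.68. ND6 of the mitochondrial genome was called higher (0.99), but 11.2% of its stranded counts lay on its own strand, and on that strand alone it changed by 0.17 (adjusted p = 0.404). In all 3802 genes passed, 1989 higher and 1813 lower. With library size as the only scaling the median of all genes moved by -0.259 and 26.4% of 4801 calls were higher, against 52.3% here.

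Next came the question of what hepatocyte Egfr loss changed at each time. At 0 h, 2 genes passed, both lower in KO. Setdb2 had 5.24 ± 2.18 CPM in WT and 0.310 ± 0.270 CPM in KO (-3.95, SE 0.543, adjusted p = 0.000453). Gm16146, named after its value was seen because only 2 genes passed, was -0.92 (adjusted p = 0.00414), with 0.834% of its stranded counts on its own strand. Of 35 lists 11 passed with the preset correlation and none with an estimated one (smallest adjusted p = 0.222). The largest of these by its median was the Kupffer cell list, lower in KO at -0.60, with 0 of 11 called (2 adjusted over the list alone; adjusted p = 1.58e-06, and adjusted p = 0.358 with an estimated correlation). DESeq2 called 24 genes, 11 of them higher, and the fit of the groups compared alone 13, 7 of them higher. The count was 14 without KO 0 h replicate 1, 5 without WT 0 h replicate 1, and 1 without KO 0 h replicate 3, where Gm16146 missed (adjusted p = 0.121).

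At 1 h, genes of fatty acid oxidation were lower in KO than in WT. Ehhadh, a peroxisomal enzyme, had 759 ± 33.4 CPM in KO and 1782 ± 306 in WT (-1.23, SE 0.189), Plin2 149 ± 29.4 and 329 ± 85.4 CPM (-1.14, SE 0.17), and Acot2 12.4 ± 3.64 and 39.2 ± 12.9 CPM (-1.64, SE 0.324). Hadha was -0.49. Of 24 PPARA targets and fatty acid oxidation genes 4 were lower and none higher (18 lower adjusted over the list alone; adjusted p = 8.49e-23, and adjusted p = 0.0207 with an estimated correlation). Hepatocyte transcription factors were lower as a list, 1 of 16 called (4 adjusted over the list alone; adjusted p = 4.81e-05, and adjusted p = 0.0207 with an estimated correlation), with Cebpa at -0.66. Heat shock genes were lower, 1 of 15 called (5 adjusted over the list alone; adjusted p = 4.68e-08, and adjusted p = 0.111 with an estimated correlation): Hspa1b had 3.25 ± 1.72 CPM in KO and 17.1 ± 2.19 in WT (-2.42, SE 0.366). Inhbe (-2.30), a hepatokine of the activin family, Lamb3 (-2.07), Cntnap1 (-1.77), the NF-kB partner Bcl3 (-1.69) and Elovl5 (-0.77) were lower. Higher in KO were Map2k6 (1.41), Cyp3a59 (1.37), the Notch coactivator Maml3 (1.20), the sterol transporter Abcg5 (1.03), Cyp3a25 (0.92), Foxo3 (0.92) and Papss2 (0.63). Papss2 makes the sulfate donor for conjugation. Phase I genes were higher as a list with 1 of 18 called (1 adjusted over the list alone; adjusted p = 0.000443, and adjusted p = 0.407 with an estimated correlation). The Kupffer cell list was higher with 0 of 11 called (0 adjusted over the list alone; adjusted p = 0.00806, and adjusted p = 0.639 with an estimated correlation), and that call was lost without the library labelled KO 1 h replicate 1 (adjusted p = 0.108). In all 65 genes passed, 18 higher and 47 lower. The count was 104 without the library labelled KO 1 h replicate 1, 16 without KO 1 h replicate 2 and 26 without WT 1 h replicate 3. Of the 18 genes named here, 12 lost their call without KO 1 h replicate 2, 10 without WT 1 h replicate 3 and 7 without WT 1 h replicate 1. Of those genes 3 each lost it without WT 1 h replicate 2, the library labelled KO 1 h replicate 1 or KO 1 h replicate 3. The count with only the groups compared in the fit was 39, and 8 of the 18 lost their call there.

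At 3 h the acute phase genes were lower in KO, 17 of 22 (20, with 1 higher, adjusted over the list alone; adjusted p = 1.89e-24, and adjusted p = 0.051 with an estimated correlation). Hp had 503 ± 49.1 CPM in KO and 1234 ± 496 in WT (-1.29, SE 0.187), Socs3 2.31 ± 0.252 and 6.95 ± 0.664 CPM (-1.59, SE 0.328), and Serpina3n (-1.86), Itih3 (-1.42), Itih4 (-1.89) and Orm1 (-1.89) were lower, as were Fgl1 (-2.29) and Acp3 (-2.19). The high list means in WT came from WT 3 h replicates 2 and 3 (8.55 and 8.67 against 6.23 in WT 3 h replicate 1). Socs3, however, was alike in all 3 WT mice. Without those 2 its fold stayed at -1.72, but its call was lost. Plasma proteins were lower, 6 of 21 (11 adjusted over the list alone; adjusted p = 2.05e-11, and adjusted p = 0.0448 with an estimated correlation), with Kng1 (-0.94), Ambp (-1.01), Vtn (-0.74) and Trf (-1.06). The red blood cell list was lower, 3 of 5 (5 adjusted over the list alone; adjusted p = 5.42e-07, and adjusted p = 0.051 with an estimated correlation): Hbb-bs had 31.6 ± 5.37 CPM in KO and 160 ± 101 in WT, and Hba-a1 was -2.25. Kupffer cell markers were lower, 1 of 11 (7 adjusted over the list alone; adjusted p = 4.32e-08, and adjusted p = 0.148 with an estimated correlation). Among the WT 3 h libraries both lists were higher in the 2 mice with high acute phase genes. The red blood cell list mean was 3.35, 4.75 and 5.07 in replicates 1, 2 and 3, and the Kupffer cell list mean 2.73, 3.32 and 3.75. The Kupffer cell list had 2.84 to 3.60 in WT at 0 h, where acute phase genes were not raised.

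Other gene groups were higher in KO at 3 h. Hepatocyte transcription factors were higher, 2 of 16 (6 adjusted over the list alone; adjusted p = 3.77e-06, and adjusted p = 0.016 with an estimated correlation), with Nr1h4 (0.67) and Prox1 (0.63). Heat shock genes were higher, 3 of 15 (7 adjusted over the list alone; adjusted p = 3.12e-07, and adjusted p = 0.103 with an estimated correlation): Hspa1b (2.52, SE 0.53), Dnaja1 (0.53) and Hspa8 (0.51), the opposite direction from 1 h. The homeobox factor Hhex had 33.5 ± 2.51 CPM in KO and 11.6 ± 4.14 in WT (1.55, SE 0.247), Fam13a was 1.40, Ier2 1.38, Gclc 0.78, Fmo1 0.53 and the pseudogene Mup-ps16 1.32. Ppfia2 (1.42) had 51.1% of stranded counts on its own strand and was 0.24 there (adjusted p = 0.916). In all 129 genes passed, 43 higher and 86 lower, and with library size as the only scaling 68 were higher and 70 lower. Without WT 3 h replicates 2 and 3, 1 WT mouse is left and the spread comes from the other groups. Most of the 129 calls then ended, and most genes called in that fit were not among the 129. Of the 26 genes named for this time Hhex (2.29, adjusted p = 0.000716) and Fam13a (1.28, adjusted p = 0.0328) were still called. Folds that lost their call but stayed near their size were Socs3 (-1.72), Hspa1b (3.02), Hspa8 (0.64), Nr1h4 (0.74), Prox1 (0.61), Mup-ps16 (1.46) and Ppfia2 (1.48). Dnaja1 (0.28) and Fmo1 (0.25) shrank, and Ier2 (1.02) and Gclc (0.61) did so less. Hp (-0.38), Serpina3n (-0.22), Itih3 (-0.18), Itih4 (-0.41), Orm1 (-0.28), Fgl1 (-0.41) and Acp3 (-0.88) shrank too. So did Kng1 (-0.13), Ambp (-0.23), Trf (-0.20), Vtn (-0.30), Hbb-bs (-0.64) and Hba-a1 (-0.48). The acute phase and Kupffer cell lists then missed (adjusted p = 0.17 and 0.307), while plasma proteins (0.0124), red blood cell (0.0341), heat shock (0.000712) and hepatocyte transcription factor (8.29e-06) lists passed. The folds of the plasma protein and red blood cell genes named here thus came mostly from the 2 mice. Leaving out single libraries gave 335 genes without WT 3 h replicate 1, 28 without replicate 2 and 9 without replicate 3, and 57, 20 and 14 without KO 3 h replicates 1, 2 and 3. The named genes that lost their call were 4, 20, 23, 14, 21 and 22. With only the groups compared in the fit 44 genes passed, 28 higher and 16 lower, and 18 of the 26 named genes lost their call, Hp (adjusted p = 0.261), Hbb-bs (0.384) and Hspa1b (0.179) among them.

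At 12 h, 7 genes passed, all lower in KO. The mitochondrial polymerase subunit Polg2 had 2.86 ± 0.553 CPM in KO and 11.0 ± 1.51 in WT (-1.97, SE 0.291), and Afm, a plasma carrier of vitamin E, 43.0 ± 1.71 and 76.4 ± 3.42 CPM (-0.83, SE 0.149). Krt78 was -1.42 and Taok3, named after its value was seen, -0.66; on the gene's own strand both just missed (each adjusted p = 0.0576). Cpm (-2.05), Mrnip (-1.47) and Ggcx (-0.70) had 53.8%, 14.7% and 83.9% of stranded counts on their own strand, and there they were -0.20 (adjusted p = 0.941), 0.60 (0.88) and 0.20 (0.668). Of 35 lists 13 passed with the preset correlation and none with an estimated one (smallest adjusted p = 0.564). PPARA targets and fatty acid oxidation genes were higher in KO with 0 of 24 called (3 adjusted over the list alone; adjusted p = 8.99e-06, and adjusted p = 0.564 with an estimated correlation). The count was 34, 0 and 28 without KO 12 h replicates 1, 2 and 3, 1 without WT 12 h replicate 2 and 13 without WT 12 h replicate 3, and 22 with DESeq2, 6 of them higher, and 24 with only the groups compared in the fit. The named genes that lost their call were 2 and 7 without KO 12 h replicates 1 and 2, and 3, 6 and 3 without WT 12 h replicates 1, 2 and 3. Averaged over the 4 times, a comparison added after the data were seen, edgeR called 0 genes, with 929 at unadjusted p under 0.05. Egfr had the smallest p (-1.51, SE 0.222, adjusted p = 0.0504), and DESeq2 called 1. Leaving out single libraries gave 32 genes without WT 3 h replicate 1, 2 without KO 0 h replicate 3 or the library labelled KO 1 h replicate 1, 1 without WT 1 h replicate 2, KO 3 h replicate 1 or 3 or KO 12 h replicate 2, and 0 otherwise.

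The last question was whether the responses themselves differed between genotypes, tested as the KO response minus the WT response. At 1 h, 60 genes differed, 21 higher and 39 lower. The response of fatty acid oxidation genes was lower in KO than in WT, with 2 of 24 called (10 lower adjusted over the list alone). The list test gave adjusted p = 4.09e-14, and adjusted p = 0.079 with an estimated correlation. Plin2 differed by -1.36 (SE 0.24) and Cpt2 by -0.66. The hepatocyte transcription factor list was lower, 2 of 16 (3 adjusted over the list alone; adjusted p = 6.9e-07, and adjusted p = 0.00747 with an estimated correlation), with Cebpa at -0.90 and Onecut2 at -0.80. Heat shock genes were lower, 2 of 15 (5 adjusted over the list alone; adjusted p = 9.63e-10, and adjusted p = 0.079 with an estimated correlation): Hspa1b by -2.63 and Hsph1 by -1.76. Lipogenesis genes were lower, 1 of 16 (5 adjusted over the list alone; adjusted p = 2.71e-05, and adjusted p = 0.079 with an estimated correlation), with Elovl5 at -1.09. Inhbe differed by -3.09 (mean CPM 27.5 to 73.4 in WT, 47.9 to 15.1 in KO) and Mfsd2a by -2.52 (32.9 to 73.5 in WT, 75.7 to 29.6 in KO), with Aqp4 (-2.39) and Bcl3 (-2.23). Setdb2 (4.27), Map2k6 (2.41), Cyp3a59 (1.94), Cyp3a25 (1.34), the pseudogene Mup-ps12 (1.61) and the NF-kB inhibitor Nfkbia (0.86) were higher, as was Cd163 (1.47), a Kupffer cell marker, with its list (1 of 11, 6 adjusted over the list alone; adjusted p = 2.57e-07, and adjusted p = 0.268 with an estimated correlation). The count was 83 without the library labelled KO 1 h replicate 1, 15 without KO 1 h replicate 2, 32 and 20 without WT 1 h replicates 1 and 3, 19 and 33 without KO 0 h replicates 2 and 3, and 35 and 27 without WT 0 h replicates 1 and 3, and 112 with DESeq2. Leaving out any single library of the 4 groups ended between 3 and 12 of the 18 named calls. These differences also hold what differed at 0 h. There the hepatocyte transcription factor list had a mean log2(CPM + 1) of 5.30 to 5.52 in KO and 5.18 to 5.23 in WT. The Kupffer cell list had 2.55 to 2.88 in KO and 2.84 to 3.60 in WT.

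At 3 h, 20 genes responded differently, 10 in each direction, a balance that changed with library size only (18 higher and 9 lower) and with DESeq2 (29 and 56). Hp (-1.49, SE 0.263), Socs3 (-2.35) and the protease inhibitor Mug2 (-1.45) were lower in this test, and 2 of 22 acute phase genes passed (15 adjusted over the list alone; adjusted p = 1.12e-13, and adjusted p = 0.236 with an estimated correlation). That list missed without WT 3 h replicates 2 and 3 (adjusted p = 0.362), a fit with 1 WT mouse at 3 h in which 6 of the 9 named genes lost their call. Hp was then -0.58 (0.371), Mug2 -0.86 (0.123) and Socs3 -2.48 (0.059). Wsb1 was -1.77, and Hmcn2 -1.63 with 5.2% of stranded counts on its own strand. Mup-ps16 (1.94), Fam13a (1.50), Clec2d (1.45) and Setd7 (1.29) were higher. The count was 142 without WT 3 h replicate 1 and 9 without replicate 3, 8, 10 and 6 without KO 3 h replicates 1, 2 and 3, 9 without KO 0 h replicate 2, and 8 and 10 without WT 0 h replicates 1 and 3. Up to 7 of the 9 named calls ended, the most without WT 0 h replicate 1 or KO 3 h replicate 3. At 12 h, 3 genes passed: the histone H1f2 (1.62), Gm16146 (1.49, named after its value was seen) and Ggcx (-1.05). The reads of Gm16146 lie on the other strand, and on their own strand H1f2 (adjusted p = 0.0942) and Ggcx (-0.15, adjusted p = 0.837) missed. That count ran from 1 without KO 0 h replicate 3, KO 12 h replicate 2, WT 0 h replicate 3 or WT 12 h replicate 1 to 15 without KO 12 h replicate 1. It was 7 without KO 0 h replicate 2, 9 without KO 12 h replicate 3, 6 without WT 0 h replicate 1 and 13 without WT 12 h replicate 3.

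Across genes, the KO and WT responses were alike in direction. The correlation across 13204 genes, which are not independent replicates, was 0.543 at 1 h, 0.671 at 3 h and 0.788 at 12 h. Genes called higher in both genotypes numbered 209, 372 and 1225, where 21.3, 49.1 and 267 are expected from the separate counts, and those called lower in both 170, 338 and 967 (expected 19.2, 43.8 and 221). Genes called in opposite directions numbered 9, 5 and 1. The slope of the KO response on the WT response was 0.562 (jackknife SE 0.0603), 0.628 (0.0372) and 0.806 (0.0236), but noise in the WT response lowers such a slope. The SD across genes of the KO response divided by that of the WT response was 1.04, 0.936 and 1.02. Noise of both genotypes enters that ratio, whatever their correlation. Neither measure shows whether the responses were of equal size. With single libraries left out the slope ran from 0.492 to 0.593, 0.566 to 0.654 and 0.754 to 0.830.

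**Figure D4:**
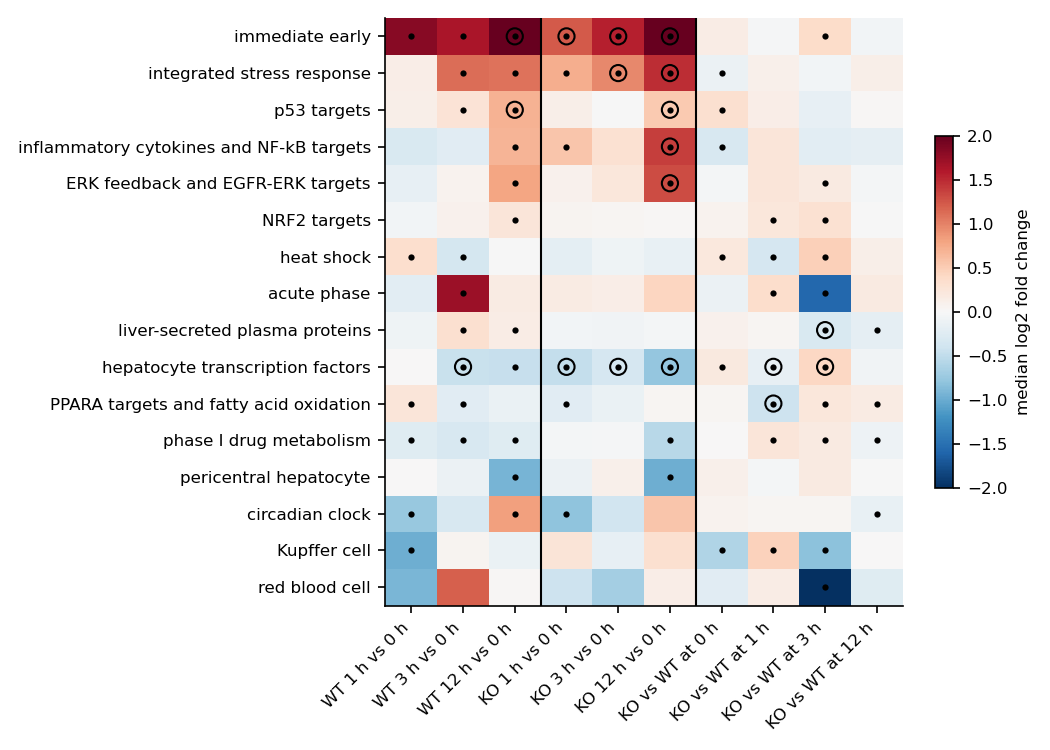
Median log2 fold change of 16 gene lists in 3 WT responses, 3 KO responses and 4 KO vs WT comparisons, on a colour scale from blue (lower) to red (higher) that saturates at 2 and -2. A filled dot marks a list with adjusted p under 0.05 at the preset correlation and a ring 1 that also passes with an estimated correlation; immediate early genes rise in every response, and acute phase genes stand out in WT at 3 h and in KO vs WT at 3 h.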

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

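The exchange of labels, the test of a WT mouse under a KO label and all splits were planned before their results were seen; the tests of the level outside WT 3 h, of neutrophil RNA, of the clock genes and of a swap at 1 h were chosen afterwards.

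Genes whose change from 0 h differed between the genotypes by a test of that difference are set out first. At 1 h, KO minus WT, these were Setdb2 (4.27), Map2k6 (2.41), Cyp3a59 (1.94), Mup-ps12 (1.61) and Cd163 (1.47) on the high side, and Inhbe (-3.09), Hspa1b (-2.63), Mfsd2a (-2.52), Aqp4 (-2.39) and Bcl3 (-2.23) on the low side, with the hepatocyte transcription factor list at a median of -0.36. For Setdb2 the WT 0 h level of 5.24 CPM against 0.310 CPM in KO makes the difference, since both genotypes were low after the drug. The transcription factor list was already higher in KO at 0 h (mean log2(CPM + 1) of 5.30 to 5.52 against 5.18 to 5.23 in WT). At 1 h it was lower in KO (4.87 to 5.00 against 5.16 to 5.23), so part of the -0.36 comes from 0 h. At 3 h they were Mup-ps16 (1.94), Fam13a (1.50), Clec2d (1.45) and Setd7 (1.29), and Socs3 (-2.35), Wsb1 (-1.77), Hmcn2 (-1.63), Hp (-1.49) and Mug2 (-1.45). Without WT 3 h replicates 2 and 3, which leaves 1 WT mouse at that time, Hp was -0.58 and Mug2 -0.86, and these 2, Mup-ps16, Fam13a, Clec2d and Socs3 lost their call. At 12 h they were H1f2 (1.62) and Ggcx (-1.05), which on the gene's own strand missed (adjusted p = 0.0942 and 0.837). Of the stranded counts of Hmcn2 5.2% lay on its own strand. In a signal outside the comparisons, the locus AY036118 held 89.8% of the opposite-strand counts at KO 1 h, where the 6 libraries at 0 h ranged from 82.5% to 88.9%.

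The first pattern is the high acute phase level of WT 3 h replicates 2 and 3. Replicate 1 had a list mean of 6.23, inside the WT 0 h range of 5.94 to 6.24. With replicate 1 alone at 3 h, the change from 0 h was 0.80 for Hp, 0.85 for Lcn2, 0.48 for Itih3 and 0.37 for Serpina3n. Whether a shared rise reached it in part stays open, as it is 1 mouse. Neutrophil RNA does not account for Lcn2, since S100a8 and S100a9 together reached at most 2.31% of its CPM. An exchange of labels with another time was tested by the nearest KO time mean. Of the 2 libraries 0 lay nearest 3 h (distances of 53.1 and 55.1 to 1 h, 56.6 and 56.2 to 3 h), which is what an exchange would give. All 10 other WT libraries lay nearest their own time. A check added after this result found 3 of 6 KO libraries at 1 and 3 h nearer the other time when left out of their own mean. Among these was the library labelled KO 1 h replicate 1. The checks disagree, so this measure cannot tell. An exchange would not account for the level in any case, as the highest list mean of the 21 libraries outside WT 3 h was 7.18 against 8.55 and 8.67, so the 2 libraries would stand out under another label too. A difference between mice, such as an inflammatory stimulus in 2 of them, and a sample from outside the set stay open.

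The second pattern is the clock genes. If the 0 h mice had been killed at another time of day, genes out of phase with Bmal1 would already differ at 1 h, and 9 of 10 gene and genotype pairs were called lower and 0 higher. A quick effect of the drug or of handling gives the same result, so this cannot tell. For a shift of clock phase alone, the genes out of phase with Bmal1 were taken to be low wherever Bmal1 is high. At 12 h Bmal1 was high (2.42 in WT and 1.84 in KO), as at 1 h (2.10 and 1.72) and 3 h (2.18 and 1.86). Of the 10 pairs at 12 h 6 were called lower (Dbp, Tef and Per3 in both genotypes) and 2 higher (Nr1d1, 0.83 in WT and 0.98 in KO). The test takes these genes to share 1 phase and does not use the course between times. It thus cannot judge a phase shift alone, which stays open. The Nr1d1 call in WT was lost without any of 4 single libraries.

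The third pattern is the Egfr level of the library labelled KO 1 h replicate 1. A swap with a WT 1 h library would leave 1 of those at a KO level, but their lowest Egfr was 332 CPM against at most 271 CPM in the other KO libraries, which speaks against a swap within this time. A WT mouse under a KO label was tested by a score over the 100 genes with the smallest p for genotype at 0 and 12 h, signed so that KO would lie higher. The library scored -0.167, WT 1 h libraries -0.0131 to 0.151 and the other KO 1 h libraries -0.046 and -0.0147, so at 1 h KO lay lower, against the sign of the score. The 0 and 12 h differences thus do not carry over to 1 h, and the score cannot tell. On the third principal component, looked at afterwards, the library lay at 3.69. The other KO 1 h libraries lay at -0.38 and -2.05 and WT 1 h at -22.4 to -14.8. More genes were called in KO vs WT at 1 h without it (104 against 65). That component does not order the genotypes alike at all times, so a WT mouse stays open. A lower share of recombined hepatocytes in this mouse would also give a high Egfr level and was not tested.

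Other splits of the same libraries were fitted to see how many calls they give. Each mixes the groups, so it keeps part of their difference and adds the rest to the spread, and its count is not that of libraries without a difference. For contrasts of 2 groups the 10 splits are too few for a share under 0.05. KO vs WT called 2, 65, 129 and 7 genes at 0, 1, 3 and 12 h where the highest other split called 0, 0, 20 and 15, and at 12 h 2 of 10 splits called as many genes as the real one. WT responses called 1068, 1865 and 3381 against at most 31, 36 and 6, and KO responses 1001, 1314 and 3802 against at most 14, 1 and 0. In those contrasts, and in KO vs WT at 0, 1 and 3 h, 1 of 10 splits, the real one, reached the count. For differences of response 1 of 100 splits reached 60 genes at 1 h (highest other 10) and 1 of 100 reached 20 at 3 h (highest other 3), while 4 of 100 reached 3 genes at 12 h (highest other 7). For KO vs WT averaged over times 0 genes were called, a count that all 100 of 100 splits must reach (highest other 1), so the splits say nothing there.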

How the results depend on the processing

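The gene-strand column, the removal of genes linked to ribosomal RNA and the removal of WT 3 h replicates 2 and 3 were chosen after the data were seen; the others were set beforehand.

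Among the counts of called genes, those of the changes from 0 h moved least. Leaving out single libraries gave 684 to 800 genes for WT at 1 h, 1255 to 1660 at 3 h and 2607 to 3206 at 12 h, and 567 to 1205, 715 to 1052 and 3105 to 3443 for KO. All lay below the main count except the 1205 in KO at 1 h, without the library labelled KO 1 h replicate 1. The cause was not tested. Outside 1.5 times the main count were WT 1 h without WT 0 h replicate 3 (710) or WT 1 h replicate 1 (684), KO 1 h without KO 1 h replicate 2 (567), and KO 3 h without KO 3 h replicate 2 (863) or 3 (715). WT 3 h gave 1198 with only the groups compared and 1027 without WT 3 h replicates 2 and 3, and WT 12 h 5324 with library size only, which moves the median of all genes.

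KO vs WT moved most. The numbers here and below are totals, and genes called in another setting need not be among the main calls. KO 1 h replicate 1 stands for the library so labelled, whose Egfr level does not follow its label. At 0 h it gave 95 genes with no filter, 24 with DESeq2, 13 with only the groups compared and 1 with the gene-strand column; 14, 1 and 5 without KO 0 h replicate 1, KO 0 h replicate 3 and WT 0 h replicate 1. At 1 h it gave 230 with no filter, 98 with DESeq2 and 39 with only the groups compared; 104 and 16 without KO 1 h replicates 1 and 2 and 26 without WT 1 h replicate 3. At 3 h it gave 254 with no filter, 121 of them also called in the main fit, and 44 with only the groups compared. It gave 57, 20 and 14 without KO 3 h replicates 1 to 3, and 335, 28 and 9 without WT 3 h replicates 1 to 3. Of the 335 genes 117 were also called in the main fit. At 12 h it gave 78 with no filter, 22 with DESeq2, 24 with only the groups compared and 2 with the gene-strand column; 34, 0 and 28 without KO 12 h replicates 1 to 3 and 1 and 13 without WT 12 h replicates 2 and 3. Averaged over times it gave 1 with RLE, 31 with no filter, 1 with DESeq2 and 1 with the gene-strand column; 32 without WT 3 h replicate 1, 2 without KO 0 h replicate 3 or KO 1 h replicate 1, and 1 without WT 1 h replicate 2, KO 3 h replicate 1 or 3 or KO 12 h replicate 2. The cause was not tested.

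Differences of response at 1 h gave 217 genes with no filter and 112 with DESeq2; 83 and 15 without KO 1 h replicates 1 and 2, 32 and 20 without WT 1 h replicates 1 and 3, 19 and 33 without KO 0 h replicates 2 and 3, and 35 and 27 without WT 0 h replicates 1 and 3. At 3 h they gave 159 with no filter and 85 with DESeq2; 9 without KO 0 h replicate 2, 8, 10 and 6 without KO 3 h replicates 1 to 3, 8 and 10 without WT 0 h replicates 1 and 3, and 142 and 9 without WT 3 h replicates 1 and 3. At 12 h they gave 79 with no filter, 29 with DESeq2, 1 with library size only, 5 with a filter of 1 CPM, 9 with only the groups compared and 0 with the gene-strand column; 7 and 1 without KO 0 h replicates 2 and 3, 15, 1 and 9 without KO 12 h replicates 1 to 3, 6 and 1 without WT 0 h replicates 1 and 3, and 1 and 13 without WT 12 h replicates 1 and 3. The cause was not tested.

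Nothing in the labels pairs the samples by replicate number, and 5 of 84 pairs of libraries with the same number correlated above 0.1 after group means were removed (-0.168 to 0.183, median 0.0095). With the number as a block, KO vs WT at 0 h gave 9 genes and the differences of response 34 at 3 h and 5 at 12 h.

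In the permutation test the lower Egfr in KO passed in every setting run, from -1.69 to -1.47 with single libraries left out. In the edgeR fit it did not pass at any single time. At 0 h it passed with DESeq2 (adjusted p = 0.000468) and with only the groups compared (0.00262). The slopes of KO on WT responses ran from 0.492 to 0.593 at 1 h, 0.566 to 0.654 at 3 h and 0.754 to 0.830 at 12 h.

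Of 144 list calls 19 kept their call with an estimated correlation and 63 with fry, which called 75 lists in all. Across lists and other settings 1190 results were the same, 279 weaker and 10 reversed; with single libraries left out 886, 163 and 1. Reversed without WT 3 h replicates 2 and 3, which leaves 1 WT 3 h library, were, in KO vs WT at 3 h, phase I (adjusted p = 0.731), phase II conjugation (0.771), immediate early (0.434), male-biased liver genes (0.307) and nuclear respiratory chain (0.346); male-biased genes in WT at 3 h (0.506); and in the 3 h difference of response phase I (0.969) and PPARA (0.836). Reversed with no filter were plasma proteins (0.896) and nuclear respiratory chain (0.785) in WT at 12 h, and without KO 0 h replicate 1 cholesterol synthesis in KO vs WT at 0 h (0.557, against 1.09e-12 without KO 0 h replicate 3). For named genes 2675 results were the same in other settings, 124 weaker and 2 reversed, and 1445 the same and 391 weaker with single libraries left out. Reversed with the gene-strand column were Mrnip (0.60) and Ggcx (0.20) at 12 h, whose counts lie in part on the opposite strand.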

Other observations

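The list tests and the test of Cyp7a1 were planned, the other values were picked after the data were seen, and all are given without explanation.

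Some cell types left little trace. No neutrophil and no B cell marker reached the test, and cholangiocyte (2 of 8), monocyte-derived macrophage (2 of 11), T and NK cell (1 of 11), pancreas (1 of 10) and adipocyte (1 of 7) markers were too few for a list test. The sinusoidal endothelium list, with 11 tested markers, was not called in any contrast. Stellate cell markers rose in WT at 12 h, 5 of 10 (adjusted p = 0.0243, and adjusted p = 0.337 with an estimated correlation), a call lost without WT 0 h replicate 2 (0.0773) or WT 12 h replicate 3 (0.0734), with library size only (0.052) and with no filter (0.355).

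Some gene groups moved in few members. Of 16 type I interferon genes 4 rose and 2 fell at 12 h in each genotype (adjusted p = 0.394 in WT and 0.647 in KO). Of 14 hypoxia genes 4 rose and 1 fell in WT at 12 h (adjusted p = 0.218). Of 9 EGFR ligands and ERBB receptors 2 rose and 2 fell in WT at 12 h (adjusted p = 0.994), and 4 rose and 1 fell in KO (0.685). The ERK target list was not called in KO vs WT at 1 h, with 0 of 14 genes (adjusted p = 0.136). At 3 h it was higher in KO with 0 of 14 genes called (adjusted p = 0.0342, and adjusted p = 0.371 with an estimated correlation). That call was lost without WT 3 h replicate 1 (0.0743), 2 (0.0971) or 3 (0.234) and without KO 3 h replicate 1 (0.204) or 2 (0.171). It was also lost with no filter (0.198), a filter of 1 CPM (0.0768), the sum of both strand columns (0.0798) or the gene-strand column (0.072). In KO at 12 h 4 of 13 genes of the mitochondrial genome rose (adjusted p = 0.0119, and adjusted p = 0.421 with an estimated correlation), a call lost without KO 12 h replicate 3 (0.0881) and with no filter (0.183). Cyp7a1, the first enzyme of bile acid synthesis, had 41.6 ± 19.1 CPM in KO and 179 ± 67.6 CPM in WT at 12 h (-2.13, adjusted p = 0.117). Saa1 had 6.47, 1100 and 735 CPM in WT 3 h replicates 1, 2 and 3.

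Gene counts were lower at 12 h, with means of 4.26 M in WT and 3.89 M in KO against 6.27 and 6.64 M at 0 h, and mitochondrial ribosomal RNA took 48.9% and 47.5% of them.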
